A study of Macaca mulatta with 38 samples.

How the data were processed

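The deposited data were 38 bulk RNA-seq libraries of neural stem cells from rhesus macaque (Macaca mulatta) fetal cortex, grown in culture. Tissue came from E42 (Anterior and Posterior) and E77 (Frontal and Occipital), and RNA was taken on 9 days in vitro at E42 and 10 at E77. Per the labels, cells grew with FGF2 up to day 5 and then differentiated without it, and RNA was pooled from 2 wells per condition. The libraries were poly(A)-selected and strand-specific by the dUTP method. There was 1 library per series and day.

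The authors deposited a table of read counts per gene and a table of RPKM values (counts divided by gene length and library total), both for 34619 genes. The submitters' processing notes name STAR and featureCounts, with no versions. The genome build and the annotation were not given in the sources used here, and the gene names are of the RefSeq style, 15986 of them provisional LOC names. The counts were whole numbers with totals from 20149635 to 56363300 (median 27597365.5), 21324987 to 34922663 at E77. The deposited RPKM values equalled counts over library total and a gene length that was the same in every library, to a coefficient of variation of at most 0.00012 over 20206 genes with RPKM of at least 0.5. Ribosomal RNA genes took 0.2861 to 1.572% of the counts and mitochondrial protein genes 0.008389 to 0.03508%. As a check for repeated samples, the spread of differences of each of 703 pairs of libraries was set against counting noise, over genes with at least 20 reads. The lowest ratio was 9.51, for the E77 Occipital libraries of days 6 and 7, and 0 pairs were under 1.5.

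Groups were series by phase, 12 in all: stem (days 1, 3 and 5), transition (6, 7 and 8) and terminal (11, 14, 17 and, at E77, 20), with the days of a phase as its replicates. Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr on the 12 groups (20794 genes tested, 13825 not tested, of which 4629 had 0 counts in all libraries), TMM factors (0.899 to 1.104), trended dispersions and robust quasi-likelihood tests, all 38 libraries in 1 fit. Phase comparisons used a model of group means (26 residual degrees of freedom), and age and region comparisons added day in vitro as a block (19 residual degrees of freedom). P-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. The labels number the libraries of a group by day, so equal numbers share a day in vitro. Deviations from the group mean correlated over 0.1 in 49 of 55 same-day pairs (-0.19 to 0.79, median 0.35), and the block was kept because the labels give the day. Days are nested in phases, so the phase comparisons have no day term and treat same-day libraries of different series as independent. Averages over series and over regions were contrasts with equal weights.

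The 18 comparisons were terminal against stem in each series and on average, transition against stem, terminal against transition, E77 against E42 in each phase, the age difference of the terminal against stem change, region within each age over all days and in the stem and terminal phases, and the region difference between ages. Region differences are Anterior minus Posterior and Frontal minus Occipital. The comparisons, the tests, the alternatives and 30 gene lists were chosen before the data were examined. Lists were tested with camera (limma 3.58.1) on log2 CPM (prior count 2) with a preset correlation of 0.01, with an estimated correlation beside it, adjusted over the lists of a comparison. Of the 30 lists 28 had genes that could be tested. List genes absent from the file were TUBB3, TLE4, CYP26B1, ZBTB20, CYP51A1, HBA2, HBG1, XIST and EIF2S3Y.

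Genes were named by a fixed rule for 6 comparisons: terminal against stem and transition against stem on average, age in the stem and terminal phases, and region over all days at each age. The rule took the 8 largest rises and the 8 largest falls among genes with a symbol that passed, reached a mean of 10 CPM on the higher side, and moved the same way in every series, region or phase. It also took, from each list, up to 4 passing genes with the largest changes, and where fewer than 2 passed, up to 2 with the highest mean. The text prints some of these genes, and others are not reported here. Genes with only 0 counts on one side were given no fold change. Other comparisons name genes already taken by the rule.

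Alternatives were DESeq2 size factors, no low-count filter, the DESeq2 Wald test (1.42.0), only the libraries compared, no day block, stem without day 1, terminal without day 20, 1 region pair at a time, each library left out in turn, and limma (trend, robust) on log2(RPKM + 1) and log2(RPKM + 0.1) for genes with RPKM of at least 1 in at least 3 libraries. Added after the data were seen were the phase comparisons without E42 Anterior and the age difference in posterior and occipital libraries alone. Like the single region pairs, these were contrasts of the remaining groups in the fit of all 38 libraries. The libraries left out of a contrast therefore still informed the dispersions and any day term. Also added was limma (trend, robust) for the phase averages on 1 value per day (mean log2 CPM over the 4 series on the 9 days they share). A correction for gene length with a loess trend per library was added too.

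The pipeline was tested on simulated data with the same groups, in which 67 genes were changed 1.5-fold, 67 genes 2-fold and 66 genes 4-fold. For terminal against stem on average it called 62.7%, 92.5% and 97% of them (20160 genes tested, 4 false calls). For transition against stem it called 71.6%, 88.1% and 98.5% (20142 genes), and for terminal against transition 67.2%, 89.6% and 98.5% (20151 genes). In single series the shares were 23.9%, 65.7% and 89.4% in E42 Anterior (20168 genes), 11.9%, 58.2% and 90.9% in E42 Posterior (20143 genes), 22.4%, 65.7% and 95.5% in E77 Frontal (20161 genes), and 20.9%, 61.2% and 77.3% in E77 Occipital (20160 genes). For age they were 43.3%, 82.1% and 93.9% in the stem phase (20128 genes) and 38.8%, 62.7% and 93.9% in the terminal phase (20135 genes), and 13.4%, 53.7% and 86.4% for the age difference (20160 genes). For region they were 61.2%, 80.6% and 100% at E42 (20144 genes), 65.7%, 83.6% and 100% at E77 (20123 genes), 14.9%, 50.7% and 80.3% in the E77 stem phase (20151 genes), 19.4%, 64.2% and 87.9% in the E77 terminal phase (20126 genes), and 19.4%, 65.7% and 93.9% for the region difference (20150 genes). False calls were 2 to 12 per comparison. Of 100 random lists of 15 genes, 0 to 3 per comparison had a camera p under 0.05. Changes of 1.5-fold were therefore mostly missed in comparisons of single groups. Genes and libraries were simulated as independent, and the simulated lists were tested on test statistics, not on log2 CPM. The false calls and list shares therefore cannot show how the tests behave with correlated genes or same-day libraries. The sheet of sample names repeated the labels and was not used.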

Results

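The libraries followed rhesus macaque fetal cortical neural stem cells from growth in FGF2 to neuronal and glial differentiation. There were 38 poly(A) RNA-seq libraries from 4 culture series: E42 Anterior, E42 Posterior, E77 Frontal and E77 Occipital, named by embryonic day of the tissue and cortical region. Each series gave 1 library per day in vitro, on 9 days at E42 and 10 days at E77. Days 1, 3 and 5 form the stem phase with FGF2, days 6, 7 and 8 the transition, and days 11, 14 and 17 (and 20 at E77) the terminal phase without FGF2. Counted reads per library ranged from 20149635 to 56363300 (median 27597365.5), and 20794 genes were tested of the 34619 in the count table. Levels are CPM, counts scaled to the library total of the tested genes times the TMM factor, with the SD over libraries. Log2 fold changes carry the standard error (SE) of the fitted model. SDs taken over several series or phases include the differences between them. The labels do not say that the libraries of a group came from separate animals, and the libraries of a series are days of what the labels name as 1 culture. Gene p-values below therefore rest on the spread between days of a culture, with the shared part of a day removed where day is a block. Camera p-values set the genes of a list against the other genes in the same libraries. Neither kind measures a spread between animals, and age and region are confounded with the fetus, the dissection and the culture run.

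The first principal component held 34% of the variance and set the E42 series, E42 Anterior furthest, against the E77 series. The second held 20.5%, and along it the libraries of each series moved with the day. Genes of mesenchymal cells set E42 Anterior apart: the type I collagen gene COL1A1, a fibroblast gene, stood at 13100 ± 4620 CPM there in the stem phase (n = 3), against 80.7 ± 47.2 in E42 Posterior, 46.4 ± 8.25 in E77 Frontal and 2.67 ± 0.12 in E77 Occipital. Haemoglobin genes of blood cells were near absent, with 0 of 6 genes in the file reaching the test and at most 2 counts of HBA1 in any library. Microglial genes were low too: 3 of the 11 listed reached the test, and the receptor gene CSF1R had at most 12 counts in a library. The sex-linked list had 8 genes in the file and 0 that could be tested, with at most 5 counts of DDX3Y in any library.

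**Figure D1:**
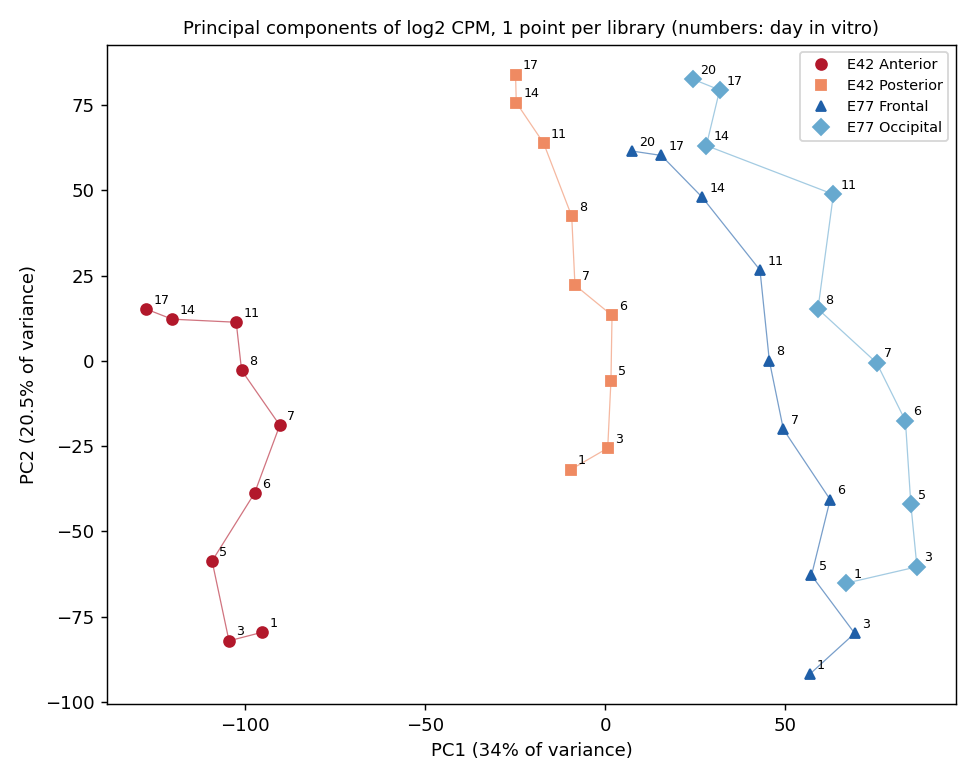
Principal components of log2 CPM in the 38 libraries, with the first component (34% of variance) on the x axis and the second (20.5%) on the y axis, coloured by culture series and labelled by day in vitro. The E42 Anterior libraries lie at the low end of the first component, and the libraries of each series move along the second with the day.

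Neuronal and synaptic genes rose most between the stem and terminal phases, averaged over the 4 series (14 terminal against 12 stem libraries). NSG2, which encodes a neuron-specific endosomal protein, rose from 10 ± 11.6 to 282 ± 156 CPM (log2 fold change 5.71 ± 0.38). The synaptic adhesion gene LRFN2 rose by 7.42 ± 0.58 on the log2 scale. The neurofilament gene NEFM rose from 65 ± 50.5 to 418 ± 113 CPM, and SNAP25, a gene of the vesicle fusion machinery, from 5.32 ± 3.57 to 35.1 ± 14.8. NOTCH1, the receptor that keeps progenitors undifferentiated, fell from 1020 ± 244 to 426 ± 88.8 CPM (log2 fold change -1.28 ± 0.08, adjusted p = 9.2e-14, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Its target HES5 fell from 89 ± 41.5 to 24.9 ± 15.4 CPM, and the replication helicase gene MCM3 from 134 ± 48 to 45.9 ± 15.2.

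The cell-type lists gave the same picture for neurons and dividing cells. Of 14 pan-neuronal genes 13 rose and 0 fell (13 and 0 adjusted over the list alone), with a median log2 fold change of 2.13 (camera, adjusted p = 7.8e-08, and adjusted p = 0.13 with an estimated correlation). Of 15 synapse genes 13 rose and 1 fell, GRIN2B, an NMDA receptor subunit gene, going from 2.01 ± 2.92 to 43.4 ± 52.7 CPM (adjusted p = 5.7e-07, and adjusted p = 0.13 with an estimated correlation). All 23 proliferation genes fell (23 adjusted over the list alone), with a median of -1.03, among them TYMS, which makes thymidylate for DNA synthesis, from 138 ± 40 to 58.2 ± 16.9 CPM (adjusted p = 5.1e-12, and adjusted p = 0.13 with an estimated correlation). Radial glia genes were split, with 3 higher, 11 lower and 2 not passing of 16 (adjusted p = 0.015, and adjusted p = 0.42 with an estimated correlation). Outer radial glia genes showed no shared direction: 4 rose and 5 fell of 9, the monooxygenase gene MOXD1 rising by 1.12 ± 0.13 and the matrix gene TNC falling from 1730 ± 1130 to 392 ± 157 CPM (adjusted p = 0.38). With an estimated correlation no list held in the 3 phase comparisons averaged over series.

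Both transmitter classes of neuron were represented among the rises. The GABAergic list had 11 of 13 genes higher and 0 lower, with a median of 1.51 (camera, adjusted p = 0.00023, and adjusted p = 0.4 with an estimated correlation). SCGN, a calcium-binding protein gene of interneurons, rose from 7.63 ± 9.67 to 111 ± 40.1 CPM, and SLC32A1, the vesicular GABA transporter gene, from 4.88 ± 5.5 to 26.8 ± 8.8. Of 14 glutamatergic genes 9 rose and 2 fell (adjusted p = 0.0048, and adjusted p = 0.13 with an estimated correlation), and the projection neuron gene NEUROD2 went from 1.04 ± 1.13 to 18.8 ± 31.7 CPM. Of 8 intermediate progenitor genes 6 rose and 1 fell, among them PPP1R17, from 4.47 ± 4.45 to 33.4 ± 35.7 CPM (adjusted p = 0.13). The Cajal-Retzius list, for early marginal zone neurons, had 3 of 6 genes higher and 1 lower (3 and 2 adjusted over the list alone, camera adjusted p = 0.27).

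Glial genes rose as well. The astrocyte list had 11 of 12 genes higher and 0 lower, with a median of 0.79 (camera, adjusted p = 0.00078, and adjusted p = 0.18 with an estimated correlation). The water channel gene AQP4 went from 32.7 ± 40.1 to 404 ± 346 CPM, and the glutamate transporter gene SLC1A2 from 9.32 ± 7.13 to 46 ± 15.9. Of 12 oligodendrocyte lineage genes 7 rose and 0 fell (adjusted p = 0.036, and adjusted p = 0.57 with an estimated correlation), and the myelin gene MBP rose by 3.72 ± 0.48, in 3 of the 4 series. Mesenchymal genes moved the other way: 7 of 10 pericyte and fibroblast genes fell and 0 rose (adjusted p = 0.0024, and adjusted p = 0.13 with an estimated correlation), as did 10 of 12 extracellular matrix genes, with 1 higher (adjusted p = 6.6e-05, and adjusted p = 0.13 with an estimated correlation). COL1A1 fell by 3.76 on the log2 scale and FN1, for fibronectin, by 2.31. Of 7 endothelial genes 1 rose and 5 fell (adjusted p = 0.2), and of 3 microglial genes 1 rose, the lysosomal gene CD68, by 0.66 ± 0.12 (adjusted p = 0.61).

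After FGF2 was removed its target list was mixed, with 8 of 15 genes higher and 3 lower (camera, adjusted p = 0.099). The phosphatase gene DUSP4, a feedback regulator of the pathway, rose from 37.3 ± 31.5 to 409 ± 194 CPM, while ETV4, a transcription factor gene induced by FGF, fell from 37.2 ± 23.6 to 8.55 ± 5.6. Rostral patterning genes rose in 6 of 9 cases and fell in 1 (adjusted p = 0.036, and adjusted p = 0.13 with an estimated correlation), SP8 by 1.31 ± 0.12. Lists without a call at this step were early progenitor temporal genes (3 higher, 7 lower of 10, adjusted p = 0.27), caudal patterning (2 higher, 4 lower of 10, adjusted p = 0.27), WNT targets (2 higher, 5 lower of 11, adjusted p = 0.28), interferon response (4 higher, 0 lower of 11, adjusted p = 0.27) and ventral forebrain and diencephalon (2 higher, 3 lower of 8, adjusted p = 0.9). Choroid plexus and cortical hem genes had 3 of 12 higher and 1 lower (2 and 0 adjusted over the list alone, adjusted p = 0.61). Late progenitor temporal genes had 3 of 9 higher and 2 lower, with a median of -0.06, a mean of 0.04 and an upward test (adjusted p = 0.9). Midbrain, hindbrain and spinal cord genes had 2 of 5 lower, with a median of 0.07, a mean of -0.82 and a downward test (adjusted p = 0.9).

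Over all genes, 6641 were higher and 6329 lower in the terminal phase, averaged over the series (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted). The counts were 3722 higher and 3370 lower in E42 Anterior, 4479 and 3704 in E42 Posterior, 4673 and 4302 in E77 Frontal, and 4494 and 4069 in E77 Occipital, with 3 or 4 terminal against 3 stem libraries each. With 1 value per day, the mean over the 4 series on the 9 days they share, limma called 5174 higher and 4604 lower. This alternative, added after the data were seen, treats same-day libraries as 1 observation, and it ended the list calls for the oligodendrocyte lineage (adjusted p = 0.053) and rostral patterning (adjusted p = 0.05). In the single series, oligodendrocyte genes rose in 10 of 12 cases in E77 Occipital (median 4.06, camera adjusted p = 5e-07, and adjusted p = 0.23 with an estimated correlation) and 10 of 12 in E77 Frontal (median 2.7, adjusted p = 0.0018, and adjusted p = 0.47 with an estimated correlation). They rose in 2 and fell in 1 in E42 Posterior (adjusted p = 0.97), and 0 rose and 5 fell in E42 Anterior (adjusted p = 0.054). Glutamatergic genes rose in 10 of 14 cases in E42 Posterior, with a median of 4.03 (adjusted p = 9.6e-07), the one neuronal list call in the 4 single series that also held with an estimated correlation (adjusted p = 0.0029). They had 4 higher and 3 lower in E77 Occipital (adjusted p = 0.84).

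Neuronal genes were higher in the transition than in the stem phase (12 against 12 libraries), and the GABAergic list already stood higher on each later day within the stem phase, before FGF2 was withdrawn. The mean log2 CPM of the GABAergic list on days 1, 3, 5 and 6 was -0.38, 1.61, 3.63 and 4.36 in E77 Occipital and 1.45, 2.95, 4.24 and 4.87 in E77 Frontal. It was 3.13, 3.95, 4.76 and 5.3 in E42 Anterior and 3.99, 4.25, 4.87 and 5.34 in E42 Posterior, with 1 library per day and no test between days. SCGN rose from 7.63 ± 9.67 to 55.9 ± 42.1 CPM (log2 fold change 3.67 ± 0.43, adjusted p = 1.8e-07, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The neuronal transcription factor gene MYT1L rose from 3.77 ± 4.22 to 21.5 ± 13.7 CPM, and STMN2, a microtubule regulator of growing axons, from 19.3 ± 22.5 to 81 ± 40.8. EOMES, the marker of intermediate progenitors, rose by 1.68 ± 0.37 and BCL11B, a deep-layer and striatal neuron gene, by 1.64 ± 0.31. Of the GABAergic list 12 of 13 rose and 0 fell, with a median of 1.55 (camera, adjusted p = 2.6e-07, and adjusted p = 0.2 with an estimated correlation). Of the pan-neuronal list 12 of 14 rose and 0 fell (adjusted p = 4.1e-08, and adjusted p = 0.2 with an estimated correlation).

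Cholesterol synthesis genes fell together between the same phases, and the list already stood lower on day 5 than on day 1, before FGF2 was withdrawn. Its mean log2 CPM on days 1, 5 and 6 was 7.89, 6.94 and 6.42 in E42 Anterior and 7.27, 6.74 and 6.31 in E42 Posterior. It was 7.17, 6.88 and 5.96 in E77 Frontal and 7.61, 6.64 and 5.84 in E77 Occipital, with 1 library per day and no test between days. All 14 fell (14 adjusted over the list alone), with a median of -0.97 (camera, adjusted p = 8.1e-10, and adjusted p = 0.2 with an estimated correlation). HMGCS1, the synthase that feeds the mevalonate pathway, went from 722 ± 203 to 281 ± 94.2 CPM, and FDPS, a later enzyme of the pathway, from 171 ± 53.6 to 65.5 ± 14.7. Proliferation genes fell in 14 of 23 cases (15 adjusted over the list alone), with 0 higher (adjusted p = 1e-05, and adjusted p = 0.26 with an estimated correlation). Glycolysis and hypoxia genes fell in 7 of 14 cases with 0 higher (adjusted p = 0.003, and adjusted p = 0.27 with an estimated correlation), among them the enolase gene ENO1, from 764 ± 172 to 469 ± 69 CPM. Genes of fibroblasts and matrix were lower too, 6 of 10 (adjusted p = 0.003, and adjusted p = 0.2 with an estimated correlation) and 8 of 12 (adjusted p = 0.00017, and adjusted p = 0.2 with an estimated correlation), with 0 higher in either list. In all, 4491 genes were higher and 4164 lower, and 2197 and 1872 with 1 value per day, where 8 of the 23 proliferation genes were lower.

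From the transition to the terminal phase synaptic and pan-neuronal genes went on rising while most GABAergic genes did not pass. Of 15 synapse genes 13 rose and 0 fell, with a median of 1.09 (camera, adjusted p = 8.6e-09, and adjusted p = 0.15 with an estimated correlation), GRIN2B by 3.43 ± 0.41 on the log2 scale. Of 14 pan-neuronal genes 9 rose and 0 fell (adjusted p = 7.3e-05, and adjusted p = 0.32 with an estimated correlation). The GABAergic list had 3 of 13 higher and 1 lower (adjusted p = 0.8). Cholesterol synthesis genes came back in part, with 13 of 14 higher, 0 lower and a median of 0.63 (adjusted p = 5.4e-05, and adjusted p = 0.45 with an estimated correlation). Against the stem phase 7 of the 14 were still lower in the terminal phase and 0 higher, with a median of -0.33 (adjusted p = 0.099), and in E42 Anterior 10 were lower. HMGCS1 rose by 0.99 ± 0.17, and its mean terminal level over the series did not differ from the stem level at the threshold (log2 fold change -0.36 ± 0.16, edgeR quasi-likelihood adjusted p = 0.0552, Benjamini-Hochberg). All 23 proliferation genes fell further, with a median of -0.67 (adjusted p = 2.7e-14, and adjusted p = 0.15 with an estimated correlation). Oligodendrocyte genes rose in 9 of 12 cases (10 adjusted over the list alone, 0 lower, camera adjusted p = 0.00083, and adjusted p = 0.45 with an estimated correlation). Over all genes 4713 were higher and 4000 lower. With 1 value per day these were 1578 and 1274, with 4 cholesterol and 4 oligodendrocyte genes higher and 0 lower in either list. With limma on log2(RPKM + 1) the balance turned, to 3490 higher and 4558 lower.

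**Figure D2:**
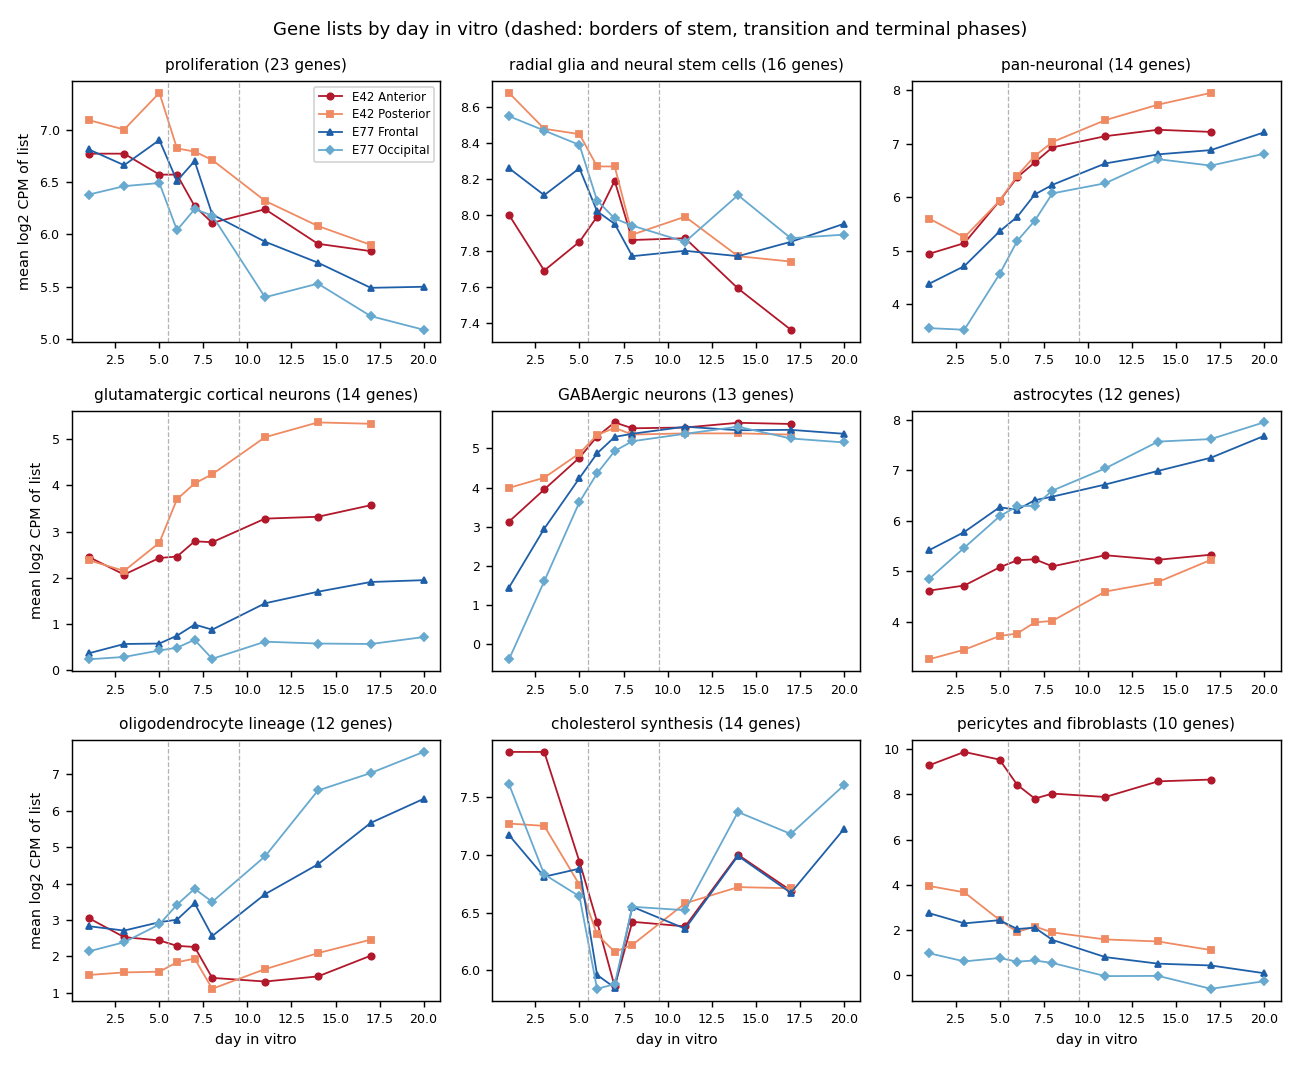
Mean log2 CPM of the tested genes of 9 lists (y axis) against day in vitro (x axis), with 1 line per culture series. Cholesterol synthesis genes dip at the transition (median log2 fold change -0.97) and come back (0.63), and the oligodendrocyte lineage rises in the E77 series.

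At the stem phase, E77 cultures carried more of the genes of outer radial glia and astrocytes than E42 cultures (6 against 6 libraries, both regions). HOPX, an outer radial glia marker, stood at 446 ± 134 CPM at E77 and 219 ± 116 at E42 (log2 fold change 1.08 ± 0.13). HEPACAM, an astrocyte adhesion gene, was at 263 ± 24.6 against 42.6 ± 10.8 CPM, and S100B, a glial calcium-binding protein gene, at 214 ± 48.3 against 24.2 ± 7.26 (log2 fold change 3.16 ± 0.11, adjusted p = 9.9e-18, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). SPP1, for the secreted protein osteopontin, was at 599 ± 515 against 14.7 ± 7.75 CPM. IGF2BP1, an RNA-binding protein gene of early progenitors, was almost restricted to E42, at 66.7 ± 18.9 CPM against 0.496 ± 0.368 at E77. The projection neuron gene NEUROD6 was at 3.23 ± 1.33 CPM at E42 against 0.0886 ± 0.0679 at E77.

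The astrocyte list had 9 of 12 genes higher and 0 lower at E77, with a median of 1.74 (camera, adjusted p = 3.2e-05, and adjusted p = 0.022 with an estimated correlation). Outer radial glia genes had 8 of 9 higher and 0 lower, and late progenitor temporal genes likewise 8 of 9 and 0, each with adjusted p = 0.00034 and adjusted p = 0.07 with an estimated correlation. The nuclear factor gene NFIX, of the late list, was at 1310 ± 409 against 778 ± 88.3 CPM. Early progenitor genes had 1 of 10 higher and 7 lower (2 and 7 adjusted over the list alone, camera adjusted p = 0.0063, and adjusted p = 0.038 with an estimated correlation). Neuronal lists were lower at E77: 10 of 14 glutamatergic genes with 3 higher (adjusted p = 0.00066, and adjusted p = 0.05 with an estimated correlation), 9 of 13 GABAergic genes with 0 higher (10 adjusted over the list alone, camera adjusted p = 0.00089, and adjusted p = 0.26 with an estimated correlation) and 11 of 15 synapse genes with 1 higher (adjusted p = 0.00031, and adjusted p = 0.05 with an estimated correlation). Choroid plexus and cortical hem genes fell in 11 of 12 cases (median -3.65, adjusted p = 8.5e-06, and adjusted p = 0.0017 with an estimated correlation), the WNT agonist gene RSPO3 by 7.64 on the log2 scale.

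Fibroblast genes differed between the ages in large part through E42 Anterior. All 10 pericyte and fibroblast genes were lower at E77, with a median of -6.16 (camera, adjusted p = 2.1e-07, and adjusted p = 0.022 with an estimated correlation), and 10 of 12 extracellular matrix genes with 0 higher (adjusted p = 3e-06, and adjusted p = 0.07 with an estimated correlation). For lists, the contrast of the posterior and occipital groups alone was added after the data were seen. There 6 of the 10 fibroblast genes were lower and 0 higher, and 4 of the 12 matrix genes were lower and 1 higher. Unfolded protein and amino acid stress genes went from 10 lower and 1 higher (adjusted p = 0.00031, and adjusted p = 0.1 with an estimated correlation) to 2 lower and 1 higher. Over all genes 5985 were higher and 6529 lower at E77 in the stem phase, and 5354 and 6462 in the transition. With limma on log2(RPKM + 1) both balances turned, to 6183 and 4441 in the stem phase and 5678 and 4528 in the transition. In the posterior and occipital contrast 8493 genes passed in the stem phase.

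In the transition the astrocyte list had 10 of 12 genes higher and 0 lower at E77 (camera, adjusted p = 7.1e-07, and adjusted p = 0.0043 with an estimated correlation). The synapse list had 1 of 15 higher and 13 lower (adjusted p = 1.4e-06, and adjusted p = 0.013 with an estimated correlation).

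In the terminal phase the oligodendrocyte lineage set the ages apart (8 E77 against 6 E42 libraries). The E77 means include the day 20 libraries, which have no E42 partner and so, with day as a block, do not inform the age contrast. OLIG2, the transcription factor gene of oligodendrocyte precursors, stood at 299 ± 188 CPM at E77 and 15.5 ± 11.9 at E42 (log2 fold change 4.24 ± 0.21, adjusted p = 1.9e-13, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). SOX10, which acts with it, was at 113 ± 85.8 against 2.88 ± 1.53 CPM, and GPR17, a gene of committed precursors, at 120 ± 94.6 against 1.99 ± 1.6. The astrocyte aldolase gene ALDOC was at 199 ± 107 against 17 ± 8.04 CPM. E42 cultures instead carried the genes of excitatory cortical neurons: NEUROD6 was at 55.3 ± 57.1 CPM against 0.516 ± 0.522 at E77 (log2 fold change -6.26 ± 0.23). EOMES was at 97.1 ± 75.9 against 4.87 ± 5.2 CPM, and RBFOX3, a gene of maturing neurons, at 16.2 ± 8.26 against 1.05 ± 1.36.

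All 12 oligodendrocyte genes were higher at E77 (12 adjusted over the list alone), with a median of 3.97 (camera, adjusted p = 6.8e-12, and adjusted p = 0.009 with an estimated correlation). Of 12 astrocyte genes 11 were higher and 0 lower (median 2.26, adjusted p = 3.4e-09, and adjusted p = 0.0011 with an estimated correlation). Of 14 glutamatergic genes 1 was higher and 11 lower (median -3.87, adjusted p = 9.1e-09, and adjusted p = 0.0012 with an estimated correlation), and all 8 intermediate progenitor genes were lower (median -2.37, adjusted p = 0.00025, and adjusted p = 0.047 with an estimated correlation). Synapse genes had 2 of 15 higher and 12 lower (adjusted p = 2.9e-06, and adjusted p = 0.014 with an estimated correlation). The GABAergic list did not separate the ages here, with 1 of 13 higher and 2 lower (0 and 1 adjusted over the list alone), a median of 0.18, a mean of -0.03 and an upward test (adjusted p = 0.71). Proliferation genes were lower at E77 in 22 of 23 cases (23 adjusted over the list alone, camera adjusted p = 1.7e-06, and adjusted p = 0.16 with an estimated correlation), the topoisomerase gene TOP2A at 199 ± 63.3 against 381 ± 71.8 CPM.

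Fibroblast genes again followed E42 Anterior, with 8 of 10 lower at E77 and 0 higher (camera, adjusted p = 4.9e-07, and adjusted p = 0.019 with an estimated correlation). Of 12 matrix genes 9 were lower and 0 higher (adjusted p = 1e-05, and adjusted p = 0.089 with an estimated correlation). In the posterior and occipital contrast, 3 fibroblast genes were lower and 1 higher, and the matrix list turned, with 6 higher and 4 lower. The direction of the oligodendrocyte and glutamatergic results did not rest on E42 Anterior. In the same contrast all 12 oligodendrocyte genes were higher, with a median of 4.344, and 10 of 14 glutamatergic genes were lower with 0 higher. E42 Anterior still informed the dispersions and day terms of that fit. Over all genes 4275 were higher and 5078 lower at E77 in the terminal phase, and 7461 passed in the posterior and occipital contrast.

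The change from stem to terminal phase itself differed between the ages for glial and neuronal genes. The change of SOX10 lay higher at E77 by 4.80 ± 0.45 on the log2 scale and that of OLIG2 by 2.22 ± 0.26 (adjusted p = 3.09e-06, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Mean OLIG2 went from 28.2 to 15.5 CPM at E42 and from 113 to 299 at E77, so the difference includes a fall at E42. SCGN rose more at E77 by 3.77 ± 0.45 and STMN2 by 2.90 ± 0.34, after lower stem levels there. Of the oligodendrocyte list the change lay higher at E77 in 9 of 12 genes and lower in 0 (10 and 0 adjusted over the list alone), with a median of 3.24 (camera, adjusted p = 2.4e-11, and adjusted p = 0.038 with an estimated correlation). Of 13 GABAergic genes 8 rose more and 0 less (9 adjusted over the list alone, camera adjusted p = 7e-06, and adjusted p = 0.19 with an estimated correlation). Glutamatergic genes rose less at E77 in 6 of 14 cases and more in 2 (2 and 7 adjusted over the list alone, camera adjusted p = 1e-04, and adjusted p = 0.038 with an estimated correlation). For NEUROD6 itself the difference of changes did not pass (log2 difference -0.94 ± 0.75, edgeR quasi-likelihood adjusted p = 0.374, Benjamini-Hochberg). In all, 2700 genes differed upward and 2747 downward, and 2305 in total in the posterior and occipital contrast. The split was 1899 and 3139 with limma on log2(RPKM + 1) and 3656 and 2170 with a gene length correction.

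**Figure D3:**
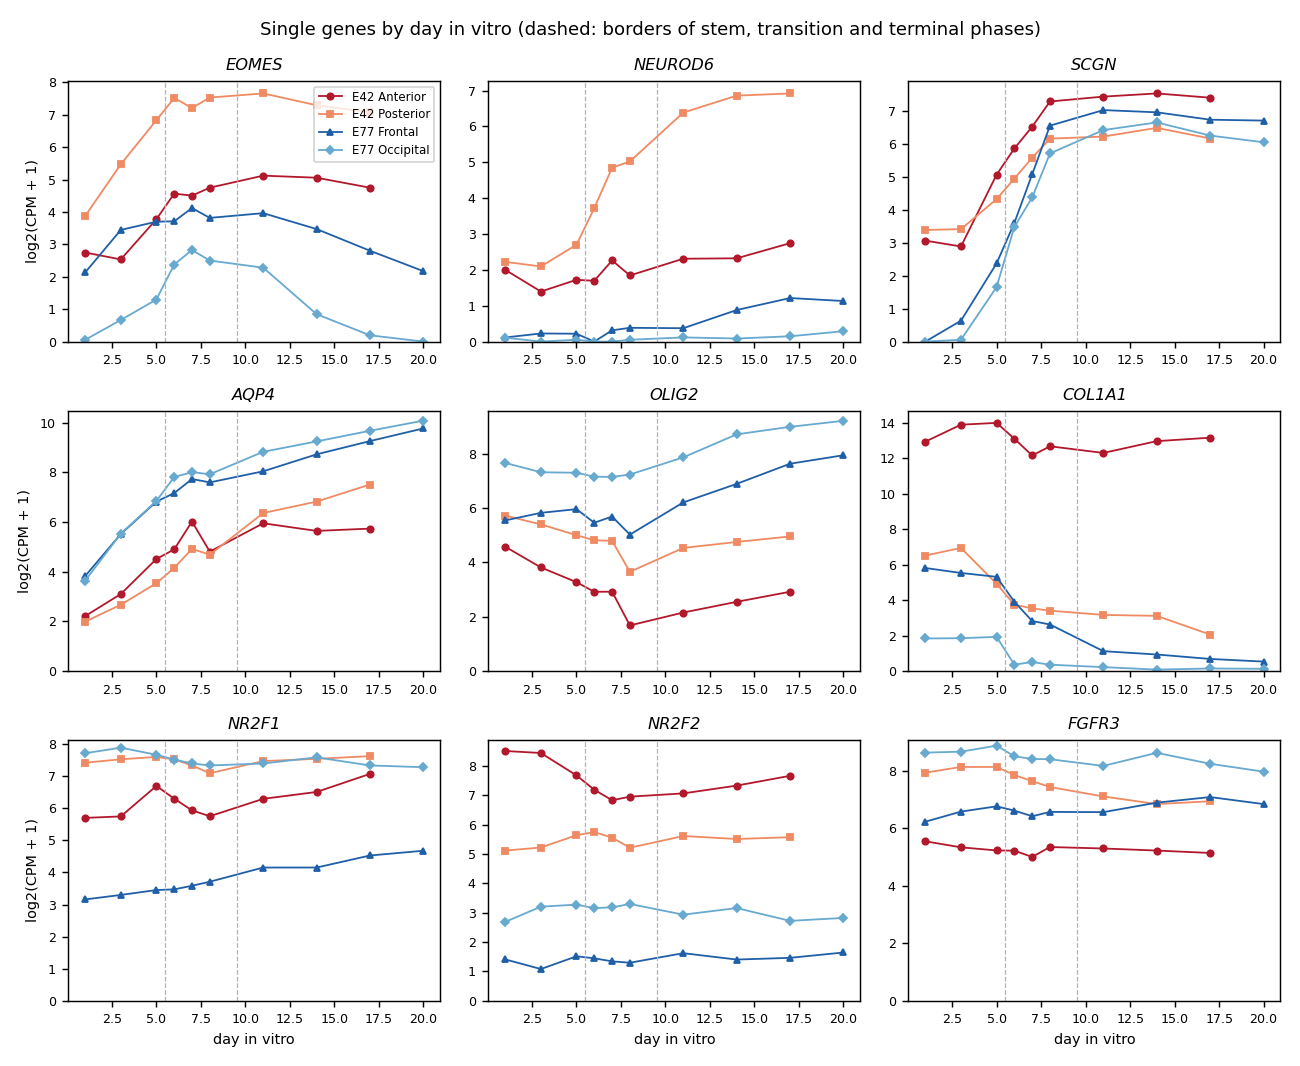
Levels of 9 genes as log2(CPM + 1) (y axis) against day in vitro (x axis), with 1 line per culture series. NEUROD6 rises in E42 Posterior to 106 CPM in the terminal phase, OLIG2 in both E77 series, and COL1A1 stays high in E42 Anterior.

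Within E42, fibroblast, matrix and vessel genes were far higher in the Anterior than in the Posterior series (9 against 9 libraries over all days). COL1A1 was at 9050 ± 4130 CPM in Anterior and 32.6 ± 43.1 in Posterior (log2 fold change 8.96 ± 0.29), and the fibronectin gene FN1 at 7140 ± 4060 against 115 ± 90.8. FOXC1, a transcription factor gene of the meninges, was at 190 ± 85.5 against 0.499 ± 0.44 CPM (log2 fold change 8.92 ± 0.13, adjusted p = 3e-26, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). All 10 pericyte and fibroblast genes were higher in Anterior, with a median of 7.35 (camera, adjusted p = 1.1e-11, and adjusted p = 0.0099 with an estimated correlation), and 11 of 12 matrix genes with 0 lower (adjusted p = 3.3e-13, and adjusted p = 0.021 with an estimated correlation). Of 7 endothelial genes 5 were higher and 1 lower (adjusted p = 0.01, and adjusted p = 0.057 with an estimated correlation), the VEGF receptor gene FLT1 by 7.07 ± 0.29.

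Posterior cultures carried more of the excitatory neuron lineage. EOMES was at 130 ± 64.1 CPM in Posterior and 20.6 ± 10.6 in Anterior, NEUROD6 at 44.7 ± 48.2 against 3.25 ± 1.25, and the upper-layer gene CUX2 at 39.3 ± 50.4 against 2.68 ± 2.44. All 8 intermediate progenitor genes were lower in Anterior (median -1.92, camera adjusted p = 0.00038, and adjusted p = 0.062 with an estimated correlation), as were 12 of 14 glutamatergic genes with 2 higher (median -1.63, adjusted p = 0.00038, and adjusted p = 0.053 with an estimated correlation). The NEUROD6 difference was -0.84 ± 0.25 in the stem phase and -4.55 ± 0.24 in the terminal phase. In the terminal phase the glutamatergic list held with an estimated correlation (adjusted p = 0.0097), with 1 gene higher and 10 lower in Anterior. Proliferation genes were lower in Anterior in 20 of 23 cases (21 adjusted over the list alone, 0 higher, camera adjusted p = 0.00038, and adjusted p = 0.37 with an estimated correlation).

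Patterning genes differed between the E42 regions one by one, not as lists. FGFR3, an FGF receptor gene expressed in a caudal to rostral gradient, was at 196 ± 64.7 CPM in Posterior and 37.3 ± 4.04 in Anterior, and NR2F1, a caudal transcription factor gene, was lower in Anterior (log2 fold change -1.23 ± 0.10). Its relative NR2F2 went the other way, at 199 ± 94.4 CPM in Anterior against 43.7 ± 6.63. Caudal patterning genes had 3 of 10 higher in Anterior and 6 lower (camera, adjusted p = 0.32), and rostral patterning genes 4 of 9 higher and 3 lower (4 and 4 adjusted over the list alone, adjusted p = 0.84). Unfolded protein and amino acid stress genes were higher in Anterior in 10 of 11 cases with 0 lower (11 adjusted over the list alone, camera adjusted p = 1.5e-05, and adjusted p = 0.064 with an estimated correlation). The chaperone pathway gene HERPUD1 was at 55.5 ± 21.2 against 19.5 ± 3.62 CPM.

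Over all genes and days 5209 were higher in E42 Anterior and 6293 lower. The balance was 3429 and 8020 with limma on log2(RPKM + 1), where the median log2 fold change of all genes was -0.131, against -0.056 in the main fit. By phase, with 3 against 3 libraries, 3855 were higher and 3531 lower in the stem phase, and 3596 and 3849 in the terminal phase. The limma splits were 2577 and 5770, and 2691 and 5028. The stem count of 7386 fell to 4781 when only the libraries compared were used.

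Within E77, NR2F1, FGFR3 and oligodendrocyte precursor genes were higher in the Occipital series, and proliferation and matrix genes in the Frontal series (10 against 10 libraries). NR2F1 was at 184 ± 26.4 CPM in Occipital and 14 ± 5.79 in Frontal (log2 fold change -3.88 ± 0.11, adjusted p = 1.8e-17, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). FGFR3 was at 352 ± 64.3 against 101 ± 17.6 CPM. The precursor genes OLIG1 and PDGFRA were at 171 ± 86.9 against 48.8 ± 33.6 and 925 ± 449 against 374 ± 92 CPM. Frontal cultures had more EOMES, at 10.1 ± 4.49 against 2.18 ± 2.28 CPM, more TYMS, at 95.5 ± 39.2 against 57.8 ± 30.1, and more FN1, at 232 ± 243 against 38.5 ± 19.8.

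Late progenitor temporal genes were lower in Frontal in 8 of 9 cases with 0 higher, with a median of -0.44 (camera, adjusted p = 9.4e-07, and adjusted p = 0.077 with an estimated correlation). Proliferation genes were higher in 19 of 23 cases with 0 lower (20 adjusted over the list alone, camera adjusted p = 9.4e-07, and adjusted p = 0.32 with an estimated correlation). Matrix genes were higher in 10 of 12 (11 adjusted over the list alone, 0 lower, camera adjusted p = 2.2e-06, and adjusted p = 0.21 with an estimated correlation), and 5 of 10 fibroblast genes with 0 lower (adjusted p = 0.0031, and adjusted p = 0.31 with an estimated correlation). Oligodendrocyte genes had 1 of 12 higher and 7 lower (2 and 7 adjusted over the list alone, camera adjusted p = 0.014, and adjusted p = 0.32 with an estimated correlation). Caudal patterning genes went both ways, with 4 of 10 higher in Frontal and 5 lower (adjusted p = 0.21), and CRYM, a thyroid hormone binding protein gene of that list, was higher in Frontal by 4.5 ± 0.5, at 0.831 ± 0.704 against 0.0261 ± 0.0258 CPM. Rostral patterning genes were higher in Frontal in 5 of 9 cases with 0 lower (5 and 1 adjusted over the list alone, camera adjusted p = 0.036, and adjusted p = 0.31 with an estimated correlation). In the terminal phase alone 11 of 12 oligodendrocyte genes were lower and 0 higher, with a median of -1.53 (adjusted p = 1.7e-09, and adjusted p = 0.045 with an estimated correlation). Over all days 3397 genes were higher in Frontal and 2865 lower.

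The E77 region counts by phase depended on single libraries and on pairing by day. In the stem phase 2504 genes were higher and 2216 lower, 4720 in total (3 against 3 libraries), and the total was 3072 without E77 Occipital stem replicate 2, the day 3 library. Without the pairing of days as a block the stem total was 2954. In the terminal phase 1648 were higher and 1180 lower, 2828 in total (4 against 4), against 1640 without the pairing.

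The region difference changed sign between the ages for EOMES and NR2F2, with Anterior set beside Frontal and Posterior beside Occipital. EOMES was lower in Anterior at E42 and higher in Frontal at E77, a difference of 5.36 ± 0.37 on the log2 scale (adjusted p = 1.86e-10, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). NR2F2 went the other way, with a difference of -4.25 ± 0.19. The NR2F1 difference was wider at E77 by -2.65 ± 0.15, and the COL1A1 difference smaller by -5.12. Of 10 fibroblast genes 0 differed upward and 9 downward (median -5.37, camera adjusted p = 4.6e-12, and adjusted p = 0.0085 with an estimated correlation). Glutamatergic genes had 9 of 14 upward and 1 downward (median 1.46, adjusted p = 1e-04, and adjusted p = 0.031 with an estimated correlation), and all 23 proliferation genes went upward (median 0.69, adjusted p = 7.5e-10, and adjusted p = 0.12 with an estimated correlation). In all, 4291 genes differed upward and 3739 downward. The split was 6642 and 2608 with limma on log2(RPKM + 1), where the median log2 difference of all genes was 0.141, against 0.052 in the main fit.

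**Figure D4:**
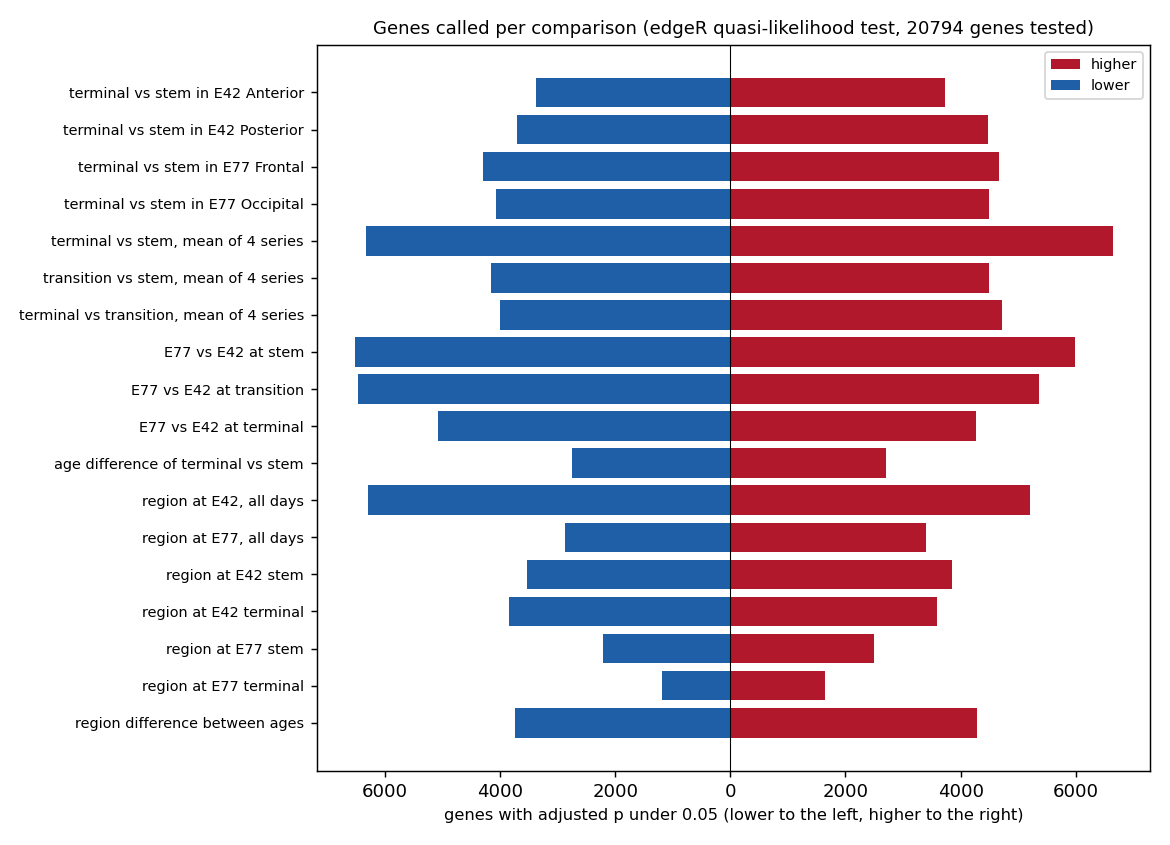
Genes past an adjusted p of 0.05 (x axis, counts) in each of the 18 comparisons (y axis), as bars for higher and lower genes. The mean of terminal against stem has the most, 6641 higher and 6329 lower, and the E77 region comparison in the terminal phase the fewest, 1648 and 1180.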

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

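Tests chosen only after their result was seen were the scaling test of the fibroblast genes, both tests of carried-over GABAergic neurons, the test of medial ganglionic eminence cells, that of gene length as the whole cause of the GABAergic rise, the equal swaps for the age difference and the splits that keep same-day libraries together or swap within days for region by phase. The other tests were chosen before their result was seen. Each SE in this section is a bootstrap over the genes of a list (2000 resamples). It measures the spread between genes of the list, not between libraries, days or cultures.

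Fibroblast genes were far higher in E42 Anterior than in E42 Posterior, with a list median of 7.35 on the log2 scale. A separate list of 12 meningeal fibroblast genes, none of them in the other lists, had a median of 2.69, with 10 higher, 0 lower and 2 not called, and 4 of the 12 were over 5 CPM in E42 Posterior as well. Its most abundant risers were CXCL12, at 555 CPM against 99.9, CDH11, at 284 against 47, and CRABP2, at 58.7 against 0.942, which suggests connective tissue cells in the E42 Anterior cultures as a candidate source. Scaling between libraries was argued against by the fibroblast list lying 7.41 (bootstrap SE 1.49) above the median of all genes tested, since a scaling factor moves every gene alike. Whether such cells came with the dissection, the region or the fetus cannot be settled by a design with 1 culture per region, and region itself stays open and untested.

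The stem to terminal change of oligodendrocyte lineage genes lay higher at E77 than at E42, with a median difference of 3.24 (bootstrap SE 1, 9 of 12 genes higher). Part of it was a fall in E42 Anterior, where the mean log2 CPM of the list was 3.05 on day 1 and 2.02 on day 17. In E42 Posterior it was 1.49 and 2.46. How much that fall added to the median was not tested. The median was 3.29 (SE 1.01) with every library thinned to 20149635 counts. Random thinning keeps the expected ratios between libraries, so this value was largely set in advance and cannot decide on depth. The median was 3.25 (SE 1.02) after the correction for gene length, which argues against that bias. The lowest median with 1 terminal day left out was 3.01 (SE 0.95, without day 17), so no single terminal day carried it. Age may explain the difference as a hypothesis, but it is confounded with the fetus and the culture run, which were not tested.

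GABAergic neuron genes rose from stem to terminal in the average of the 4 series (median 1.51), although the list was not called in E42 Posterior alone (camera adjusted p = 0.18). Neurons carried over at plating were looked for by the median log2 ratio of terminal days to day 1. It was 2.37 (SE 0.51) in the lowest of the other 3 series and 1.05 (SE 0.34) in E42 Posterior. Day 1 is itself a stem day from which the rise is measured, so a ratio in that direction was largely set in advance. The ratio therefore cannot decide whether neurons were carried over, which stays open in all series. Cells of the medial ganglionic eminence were argued against as the source of the whole rise by NKX2-1 and LHX6, which reached at most 0.687 CPM (of the plain library total, without TMM factors) in any library, although NKX2-1 rose by 3.39 and SST by 1.97 at such low levels and the tested genes of that list had a median of 0.95. The correction for gene length took -0.01 (SE 0.02) from the median gene of the list, which argues against length as a cause of the median rise. It took at most 0.46 from any gene tested, so a part in the rise of single genes stays open. The median after correction, 1.5 (SE 0.52), was above the bound of 1 set in advance, but within its spread between genes of that bound. The larger rise at E77 (8 of 13 genes) leaves age confounded with the fetus and the culture run.

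In groups of 4 libraries, 74 comparisons of 1 library with the others of its group were made, and 3 stood apart, where chance gives about 1 in 20. The TMM factor of the E77 Frontal day 20 library was 0.942, against 1.018 to 1.032 in the other terminal days. The mean log2 CPM of the radial glia list was 8.11 in the E77 Occipital day 14 library, against 7.85 to 7.89. That of the endothelial list was -0.81 in the E77 Occipital day 11 library, against -1.64 to -1.5.

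A pair of tests asked whether an effect differed between the ages. The stem to terminal change differed in 5447 genes and the region difference in 8030.

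Other splits of the same libraries were counted for each number of called genes. For E77 Frontal terminal against stem (8975 genes, highest other split 7499, of 35) and E77 Occipital (8563, 7645, of 35) 1 split was as large, the real one. That held too for age in the stem phase (12514, 8715, of 32), the transition (11816, 7409, of 32) and the terminal phase (9353, 9028, of 64). It also held for region at E42 (11502, 8952, of 100), region at E77 (6262, 3853, of 100) and the region difference (8030, 4856, of 100). The other splits mostly mix days of different cultures, or early and late days of 1 culture. The real split therefore tends to be largest wherever cultures differ or drift over days, and these counts do not decide on chance. For age and the region difference they also take same-day libraries of different series as independent. With 1 culture per series, no split of its days can address chance differences between cultures or fetuses. For region in the E77 terminal phase (2828 genes) the highest of the other 4 against 4 splits, 35 in all, was 1116, but those splits ignore the pairing by day, and swaps within days are 8 (highest other 110), too few for a share under 0.05. For the averages over the 4 series chance stays open as well. Splits drawn within each series gave 1 of 100 as large for terminal against stem (12970 genes, highest other 10910), transition against stem (8655, 6464) and terminal against transition (8713, 5406), but they treat same-day libraries of different series as independent. With same-day libraries moved together the splits were too few for a share under 0.05: the highest other was 11079 of 20 splits, 2063 of 10 and 6398 of 20 in the same order. With 10 splits each, the splits were likewise too few for a share under 0.05 for E42 Anterior (7092, 154), E42 Posterior (8183, 0), region in the E42 stem phase (7386, 360), region in the E42 terminal phase (7445, 1) and region in the E77 stem phase (4720, 62).

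For the age difference, swaps with as many pairs in the stem as in the terminal phase gave 1 split as large (the real one, 5447 genes) of 100, with a highest other of 2166. Most other swaps mix days of different cultures, so the real split tends to be largest wherever cultures differ in their course. The count therefore does not decide on a chance assignment of age labels. It also takes the regions of a day as independent and cannot address chance differences between cultures or fetuses. That scheme replaced the one set in advance, in which the pairs of each phase were swapped freely and the real count was reached by other splits. A free swap that exchanges more pairs in one phase than in the other carries part of the age contrast into the difference. The count was reached in all 4 free splits with a difference of 4 pairs (5684 to 8985 genes), in 1 of 10 with a difference of 3 and in 1 of 37 with a difference of 1. It was reached in 0 of 26 with equal numbers, where the highest was 1493.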

How the results depend on the processing

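The alternatives added only after the data were seen were those without E42 Anterior, the age difference in posterior and occipital libraries alone, the phase averages with 1 value per day, and the correction for gene length. The 18 counts of called genes were computed under up to 14 settings, giving 167 values, of which 6 differed from the main count by over 1.5 times. With only the libraries compared, region in the E42 stem phase gave 4781 genes (main 7386). That setting leaves fewer libraries to estimate the spread. It gave no separate value for the region difference, which uses all libraries. The posterior and occipital contrast of the age difference gave 2305 (main 5447), with fewer groups compared in the fit of all 38 libraries. With 1 value per day, the mean over the series, transition against stem gave 4069 (main 8655), terminal against transition 2852 (main 8713) and terminal against stem 9778 (main 12970). That setting has fewer observations and also uses limma on mean log2 CPM in place of edgeR on counts, and the changes were not tested apart. Of the named values 190 stayed as they were under it and 39 were weaker. Without E42 Anterior in the contrast, but with all 38 libraries in the fit, the phase counts were 12494, 7487 and 8520.

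Without the replicate block (no day term), region gave 2954 genes in the E77 stem phase (main 4720) and 1640 in the E77 terminal phase (main 2828). Leaving out the block changed no other age or region count by over 1.5 times. The phase comparisons have no day term, so this setting gave no value for them.

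Leaving out each library in turn gave 268 counts, of which 1 moved by over 1.5 times: region in the E77 stem phase without E77 Occipital stem replicate 2, the day 3 library (3072). The ranges for terminal against stem were 5464 to 7344 in E42 Anterior, 6144 to 7810 in E42 Posterior, 7323 to 9256 in E77 Frontal, 6949 to 9257 in E77 Occipital and 12654 to 13196 on average. They were 7969 to 8847 for transition against stem and 7910 to 9462 for terminal against transition. For age they were 11597 to 12555 in the stem phase, 10711 to 11304 in the transition, 8531 to 9457 in the terminal phase and 4277 to 6692 for the age difference. For region they were 10671 to 11405 at E42, 5702 to 6412 at E77, 5689 to 6812 in the E42 stem phase, 5504 to 6714 in the E42 terminal phase, 3072 to 4763 in the E77 stem phase, 2082 to 2775 in the E77 terminal phase and 7407 to 8150 for the region difference.

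The balance of higher and lower genes moved by over 10 percentage points in 17 cases. The limma settings on RPKM scale by the plain library total, without TMM factors, and use another gene filter. These differences from the main fit were not tested apart. With limma on log2(RPKM + 0.1) the splits were 3397 higher and 4566 lower for terminal against transition, 6203 and 4500 for age in the stem phase, 5627 and 4510 in the transition, 1916 and 3059 for the age difference, 3499 and 8115 for region at E42, 2682 and 6010 in the E42 stem phase, 2716 and 4988 in the E42 terminal phase, and 6670 and 2561 for the region difference. The median log2 fold change of all genes was then -0.162 for region at E42 (main fit -0.056) and 0.176 for the region difference (main fit 0.052). It was -0.196 and -0.147 in the E42 stem and terminal phases (main fit -0.048 and -0.066). With log2(RPKM + 1) the median was -0.153 and -0.117 in the E42 stem and terminal phases. With the length correction the median was -0.104 for age in the stem phase (main fit -0.025).

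Of the named genes, 11 log2 fold changes changed sign, and the cause was not tested. They were ADM for terminal against stem with limma on log2(RPKM + 1) (0.02), GLI3 (0.17) and EOMES (0.06) for age in the stem phase with anterior and frontal libraries alone, and with posterior and occipital libraries alone ADM (1.56), TEK (1), NOTUM (0.81), NDRG1 (0.78) and NR2F1 (0.26) in the stem phase, and TGFBI (1.55), TEK (0.73) and NPY (-0.58) in the terminal phase. The DESeq2 size factors left 691 named values as they were and 1 weaker, the Wald test 685 and 4, no filter 680 and 12, and the length correction 684 and 7. Leaving out each library left 12812 and weakened 273, with 0 changes of sign. Depth limits genes with few counts, and 13825 of 34619 were not tested.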

Other observations

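The alternatives without E42 Anterior and with posterior and occipital libraries alone, for lists and for the age difference, were chosen only after the data were seen. They were contrasts within the fit of all 38 libraries.

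The cholesterol gene HMGCS1 was lowest in the transition in every series. This synthase gene stood in the stem, transition and terminal phases at 712, 266 and 355 CPM in E42 Anterior and at 678, 255 and 455 in E42 Posterior. It stood at 619, 282 and 626 in E77 Frontal and at 880, 322 and 950 in E77 Occipital. The signed terminal minus stem change of HMGCS1 lay higher at E77, where the terminal means were near the stem means, by 0.57 ± 0.21 on the log2 scale (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0476). Of 14 cholesterol genes 7 differed upward and 0 downward (10 adjusted over the list alone, camera adjusted p = 0.00077, and adjusted p = 0.57 with an estimated correlation).

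The E42 Anterior series, which also carried the fibroblast genes (list median 7.35, COL1A1 at 9050 ± 4130 against 32.6 ± 43.1 CPM), differed from E42 Posterior in other lists, and their cell of origin was not tested. Of the WNT targets, 6 of 11 were higher in Anterior and 1 lower (camera, adjusted p = 0.041, and adjusted p = 0.25 with an estimated correlation). The transcription factor gene LEF1 was higher by 2.77 ± 0.19 and the feedback gene AXIN2 by 0.91 ± 0.09. Interferon response genes were higher in Anterior in 8 of 11 cases and lower in 1 (adjusted p = 0.0043, and adjusted p = 0.25 with an estimated correlation), IFIT1 at 5.5 ± 1.55 against 1.61 ± 0.495 CPM. Glycolysis and hypoxia genes had 6 of 14 higher and 1 lower (adjusted p = 0.041, and adjusted p = 0.35 with an estimated correlation). The antiviral gene MX1 was higher at E77 in the terminal phase, at 28.6 ± 7.81 against 10.1 ± 1.65 CPM.

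SOX10 was not restricted to the E77 series: it stood at 9.45, 21.9 and 1.83 CPM in the stem, transition and terminal phases of E42 Anterior, at 3.5, 7.04 and 59.2 in E77 Frontal, and at 4.41, 18.8 and 168 in E77 Occipital. Without E42 Anterior, 9 of 12 oligodendrocyte genes rose from stem to terminal on average and 0 fell, and 1 of 14 cholesterol genes rose and 2 fell, against 0 and 7 with all 4 series.

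Ribosomal RNA took the largest share of counts in E42 Anterior on days 7 (1.572%) and 8 (1.218%), against a median of 0.5462% over the libraries. The gene MIR663-6 took 0.1559 to 0.702% of the counts.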
